A study of Arabidopsis thaliana with 16 samples.

How the data were processed

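The series measured steady-state RNA in whole Arabidopsis thaliana seedlings of 2 genotypes, the Col-0 wild type (WT) and a phyA null mutant, in 3 light conditions. Seedlings grew in continuous white light for 5 days, per the labels' protocols, and then spent 24 h in white light, in shade or in strong shade. The 16 arrays fall into 6 groups, with 2 arrays per genotype in white light and 3 per genotype in each shade. Group and replicate number were taken from the sample labels alone.

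The deposited values are probe set intensity values on a linear scale, made with RMA in the affy package per the submitters' processing notes; versions are not given in the sources used here. RMA as usually run returns log2 values, but the deposited intensity values lay between 2.33 and 6167 and were read as linear. Array medians lay between 13.5 and 15.1. The log2 of each deposited intensity value was taken before any test, with no pseudocount, so every fold change here is a difference of log2 intensity. No further scaling was applied, and all 22746 probe sets were tested. The number of arrays limits the precision, and fold changes of probe sets close to the lowest intensities understate the change in RNA, because RMA compresses dim signals. Background intensity per probe set is not given in the sources used here.

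Probe sets were named through the supplied platform annotation and a reference gene table of assembly TAIR10.1, which served for names only. Of the 22746 probe sets, 13513 had 1 gene listed, 503 had several and 8730 had none listed, and those without a single gene are unnamed here. Of the 13513, 13436 matched the reference table and 77 did not. The symbol of 11933 was only a locus tag, and such genes appear under that tag. The 13513 probe sets stood for 13356 genes, and a gene with several probe sets was represented by the one with the highest mean over the 16 arrays. No genome build is named for the arrays, so no coordinates are given.

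Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 16 arrays, so that the 6 groups shared an estimate of spread with 10 residual degrees of freedom, and was moderated with eBayes. The 12 comparisons were shade and strong shade against white light and against each other within each genotype, phyA against WT in each light, and the 3 differences of these differences. Benjamini-Hochberg adjustment ran over all 22746 probe sets within a comparison, and a probe set was called at adjusted p under 0.05. All adjusted p-values of single genes are limma's, and values after ± are the standard error of a log2 difference or, for group means, the SD.

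Before the data were examined, 26 gene lists with 460 entries were fixed, of which 66 entries were measured by a probe set with 1 gene; 1 entry was dropped because its name and locus differed in the reference table. Of the lists, 4 had no measured member. The lists with at least 5 measured members were tested with limma's camera, with 1 probe set per gene, a preset correlation of 0.01 between genes, and again with an estimated correlation. These were the auxin early-response, expansin and XTH, photosynthesis, chlorophyll metabolism, and flavonoid and anthocyanin lists; adjustment ran over the 5 lists and 12 comparisons. Smaller lists were only counted. A further list of cytosolic ribosomal protein genes was left out because the reference table gives no descriptions. The counts adjusted over the list alone treat only the members of that list as tested. Also, 31 families of genes that share the letters of a symbol, or are encoded in the plastid, were tested in the same way, with at least 8 members each and adjustment over 372 tests; they were chosen after the annotation had been seen.

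Named genes followed a rule fixed before the data were examined. In each comparison these were the 6 highest and 6 lowest log2 fold changes among called probe sets with 1 gene whose arrays did not overlap between the groups, the overlap condition not being applied to the differences of responses. Up to 4 members of each list with the largest changes in a comparison were added, together with members named in an earlier comparison and all measured shade-induced genes. Families and the probe sets called in all 3 lights fall outside the rule and were chosen after their values were seen.

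The alternative settings were median centring of each array, cyclic loess, leaving out the dimmest 40% of probe sets, trended and robust variances, array weights, a model on only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, 1 probe set per gene, and leaving out each array in turn. Leaving out the third phyA arrays of both shade conditions together was added after the data had been seen. With 1 of the 2 white-light arrays of a genotype left out, the remaining array is assumed to vary like the other groups.

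The procedure was tested on simulated data built from the mean of each real probe set over all 16 arrays and its spread within groups. The simulated groups differed only in the probe sets that were changed. For a log2 change of 1 in 67 genes, 77.6% were recovered for WT shade against white light, 82.1% for WT strong shade against shade, 82.1% for phyA against WT in white light, 88.1% for phyA against WT in strong shade and 34.3% for the difference between the strong shade responses. For a log2 change of 2, recovery lay between 94.0% and 100%. False calls made up 2.20% to 6.16% of calls in the simulated comparisons. Few probe sets were changed there, and the simulated WT shade comparison with white light gave 137 calls, against 8284 in the real one. The adjustment depends on how many change, so these shares do not carry over to comparisons with many calls. Of 20 simulated lists without a shift, camera called 0, and it called the shifted list. Simulated values varied independently between genes, so these camera results do not extend to lists of correlated genes.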

Results

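RNA levels were measured on 16 Affymetrix arrays of whole seedlings. Phytochrome A is the photoreceptor that responds to far-red light, and the series asks what part it takes in the response of seedlings to the shade of other plants. White light was supplied at 45 µmol m-2 s-1. Shade came from LEDs with red at 13, blue at 3.5 and far-red at 21 µmol m-2 s-1, a red to far-red ratio of 0.7. Strong shade had red at 3, blue at 3.5 and far-red at 30 µmol m-2 s-1, a ratio of 0.1. White light and the LED conditions thus differed in source as well as in ratio. A difference from white light therefore belongs to the whole change of light together with any batch of white-light samples, which the labels leave open. The 6 groups held 2 WT and 2 phyA arrays in white light and 3 arrays of each genotype in each shade. The labels do not say whether replicates came from separate batches of seedlings, so the p-values measure only the spread between these samples, which may be technical. No probe set could be named as PHYA, because the annotation used lists no probe set for that gene alone. The genotype labels therefore have no check from a probe set known to measure the mutated gene.

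The main axis of a principal component analysis held 70.2% of the variance and parted the 4 white-light arrays from the other 12, and the next axis held 10.6%. Across probe sets, which are not independent replicates, arrays of the same group correlated at r = 0.979 to 0.995, and white-light arrays correlated with the others at 0.894 to 0.946. Among the phyA arrays in shade, 2 stood apart from their groups. The third array labelled phyA shade correlated at 0.986 with the other phyA shade arrays and at 0.994 with arrays 1 and 2 of phyA strong shade. The third array labelled phyA strong shade correlated at 0.981 with its own group and at 0.991 with arrays 1 and 2 of phyA shade. A score was built from 306 probe sets that were higher and 542 that were lower in WT strong shade than in WT shade. They were called in a separate model of those WT arrays alone, which the score therefore parts by construction. On this score the phyA shade arrays lay at -0.70, -0.71 and 0.63, and the phyA strong shade arrays at 0.31, 0.77 and -1.02. The number of calls in each comparison that uses these groups is therefore also given without the third arrays, a choice made after the data had been seen. Values of single genes, lists and response ratios include the third arrays unless stated, and some move without them. CaS in phyA against WT in strong shade stood at -2.82 ± 0.483 with them and at -3.57 ± 0.199 without.

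**Figure D1:**
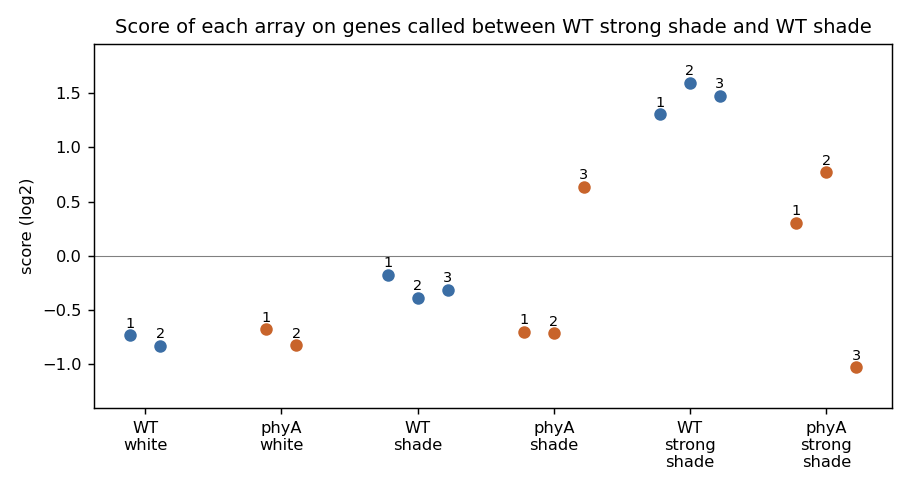
Score of each of the 16 arrays (y axis, log2) by group (x axis), with replicate numbers beside the points. The score uses probe sets called between WT strong shade and WT shade in a model of those arrays alone, so it parts these 2 groups by construction. The third phyA shade array lies at 0.63 and the third phyA strong shade array at -1.02, each on the side of the other group's arrays.

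Shade against white light in WT compared normal seedlings between the lights, with any batch of white-light samples included in the difference. IAA29, an auxin response repressor gene, rose by 4.91 ± 0.405 (adjusted p = 1.52e-07), and WES1, which encodes an enzyme that conjugates auxin, by 3.73 ± 0.128 (adjusted p = 2.9e-11). Also higher were MCCA of leucine catabolism at 4.69 ± 0.349 and MGL, a methionine gamma-lyase gene, at 4.77 ± 0.243, beside the linker histone gene HIS1-3 at 5.46 ± 0.309 and AT5G39520 at 5.92 ± 0.34. GAT1_2.1 rose by 4.97 on its brighter probe set and by 1.44 on the other. BCAT4, which acts in the synthesis of methionine-derived glucosinolates, fell from a log2 intensity of 9.06 in white light to 2.65 in shade. GSTU20, a glutathione transferase gene, fell by 5.89 ± 0.311, and AT1G73600, a phosphoethanolamine N-methyltransferase gene, fell by 5.11 ± 0.168. In strong shade against white light MCCA stood at 5.31, AT5G39520 at 5.71, GSTU20 at -6.28 and BCAT4 at -5.96.

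Shade, auxin and low-energy lists had more members higher than lower in WT in both lights. All 3 measured shade-induced genes rose in shade: HAT2, a homeodomain gene, by 1.76, FHL, which acts in nuclear import of phytochrome A, by 1.66, and IAA29. In strong shade HAT2 and IAA29 rose, and FHL stood at 0.55 (adjusted p = 0.0981); adjusted over the list alone, 3 passed in each light. Of 6 measured auxin early-response genes, 4 rose in shade (camera adjusted p = 0.00971, and adjusted p = 0.106 with an estimated correlation) and 3 in strong shade (0.0158, and adjusted p = 0.12 with an estimated correlation), with the same numbers adjusted over the list alone. In shade GH3.3 lost its call without WT white 2 (adjusted p = 0.0658) and GH3.17 without WT white 1 or WT shade 3 (up to 0.179). In strong shade GH3.17 lost its call without WT white 1 or WT strong shade 1 or 2 (up to 0.246), and after cyclic loess (0.085). The gibberellin receptor gene GID1A rose by 1.76 and 1.79. All 3 measured dark and low-energy genes rose in both lights, here MCCA, AKINBETA1 at 3.11 and 3.58, and PPDK at 3.05 and 3.67, and all 3 glucosinolate genes fell; the numbers adjusted over each list alone were the same. The clock gene GI rose by 2.21 in shade and 2.39 in strong shade.

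Lists of cell wall, chloroplast and pigment genes had more members lower than higher in WT. Of 10 expansin and XTH genes, which act on the cell wall, 4 fell in shade (adjusted p = 0.0325, and adjusted p = 0.426 with an estimated correlation) and 7 in strong shade (0.000534, and adjusted p = 0.217 with an estimated correlation), or 4 and 8 adjusted over the list alone. EXPB3 stood at -4.35 and -4.66, EXPA15 at -2.35 and -2.82, and XTH20 at -2.01 and -2.10. Of 5 chlorophyll metabolism genes, 4 fell in shade (adjusted p = 0.00401, and 0.0375 with an estimated correlation), among them CHLI2, a magnesium chelatase gene, at -2.60 and PORB, a protochlorophyllide reductase gene, at -1.32. In strong shade 3 fell and HEMA2 rose by 1.10 (adjusted p = 0.0158, and adjusted p = 0.081 with an estimated correlation); adjusted over the list alone, 4 were lower and 1 higher in each light. All 5 flavonoid and anthocyanin genes fell in shade (adjusted p = 0.00971, and adjusted p = 0.0877 with an estimated correlation). In strong shade 3 of them fell, or 4 adjusted over the list alone (camera adjusted p = 0.0446, adjusted p = 0.164 with an estimated correlation, and 0.0642 without the third phyA arrays). Of 6 photosynthesis genes, 3 were lower in shade, where the list missed the threshold (0.0625), and 4 in strong shade (0.0487, but adjusted p = 0.148 with an estimated correlation and 0.0562 with the replicate block). Of 3 root marker genes, 2 fell in shade and 3 in strong shade, also adjusted over the list alone, with EXPA18 at -1.59 and -1.85.

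Several of these counts rest on single arrays. In shade PSAN and PSAE-1 both lost their calls without WT white 1 (adjusted p up to 0.122 and 0.109), which leaves LHCB4.3 of the 3 photosynthesis calls, and PSAN also without WT white 2 or WT shade 1. In strong shade LHCB4.3 lost its call without WT white 1 (0.101) and LHCB4.1 without WT white 2 or WT strong shade 1 (up to 0.21) or with the replicate block (0.0501). The root marker gene EXPA7 lost its call without WT white 1 in both lights (0.0564 and 0.0586), and PYK10 in strong shade without WT white 2 (0.097). Of the flavonoid calls in strong shade, UF3GT ended without WT white 1 (0.115).

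Over all probe sets, limma called 3835 higher and 4449 lower in WT shade than in white light, and 4097 higher and 4825 lower in strong shade. Centring each array on its median moved the share that was higher in strong shade from 45.9% to 57.3% and set the median of all probe sets at 0.125, so small shifts there depend on the scaling. Of the members counted above, PSAN in shade and LHCB4.1 and UF3GT in strong shade lost their calls with this centring (adjusted p = 0.0561, 0.15 and 0.063).

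**Figure D2:**
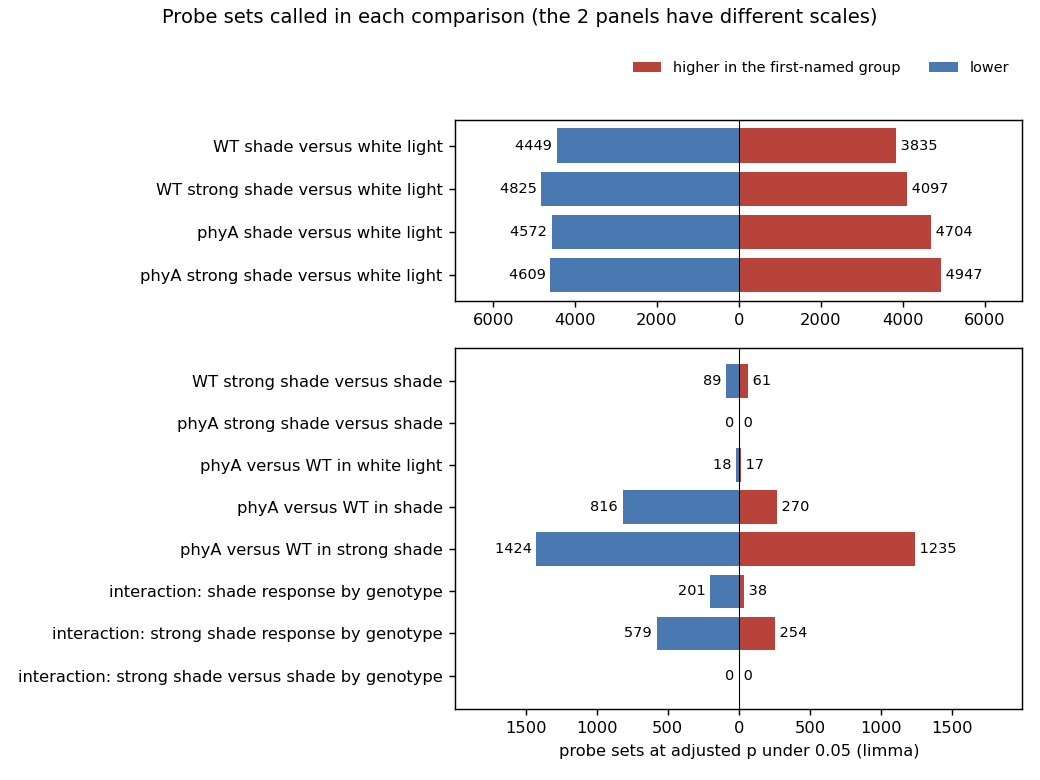
Number of probe sets called by limma at adjusted p under 0.05 (x axis) in each of the 12 comparisons (y axis), with those higher in the group named before "versus" to the right and those lower to the left. The 4 comparisons with white light hold between 8284 and 9556 calls each, drawn on a wider scale than the other 8, of which 2 hold 0.

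In phyA seedlings the same comparisons with white light asked whether the response needs phytochrome A. AT5G39520 rose by 7.43 in shade and 7.27 in strong shade, MGL by 5.61 and 5.87, HIS1-3 by 5.56 and 5.49, and IAA29 by 4.28 and 3.97. BCAT4 stood at -6.23 and -5.73, GSTU20 at -5.63 and -5.57, and AT1G73600 at -5.41 and -5.28. FHL rose by 3.90 ± 0.251 in both lights (adjusted p = 6.6e-09 and 6.04e-09), and HYH, which encodes a bZIP factor related to HY5, fell by 2.50 ± 0.138 and 2.47 ± 0.138.

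All 6 photosynthesis genes fell in phyA in strong shade (adjusted p = 0.000363) and 5 in shade (adjusted p = 0.00151), among them RCA, the rubisco activase gene, at -1.58 and -1.31. Of 5 chlorophyll metabolism genes, 4 fell in each light (0.00103 in shade, 0.00164 in strong shade), with CHLI2 at -3.56 and -3.54, and HEMA2 was higher at 0.44 in strong shade. All 5 flavonoid genes fell in both lights (0.000363 and 0.000424), with DFR, the dihydroflavonol reductase gene, at -2.68 and -2.63. Adjusted over each list alone, the photosynthesis, chlorophyll and flavonoid numbers were those of the counts over all probe sets. Of the auxin early-response genes, 3 of 6 rose in each light (adjusted p = 0.0155 and 0.0106, but adjusted p = 0.12 and 0.107 with an estimated correlation), and 3 in each adjusted over the list alone. Of the expansin and XTH genes, 2 rose and 4 fell in shade, or 5 adjusted over the list alone, where the list missed the threshold (0.0788). In strong shade 2 rose and 6 fell, also adjusted over the list alone (0.0467, but adjusted p = 0.449 with an estimated correlation, and 0.0596 after cyclic loess). The shade-induced, gibberellin, dark and low-energy and root marker lists had all of their 3, 2, 3 and 3 measured members called in both lights, the last lower and the others higher.

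The calls numbered 4704 higher and 4572 lower in phyA shade, and 4947 higher and 4609 lower in phyA strong shade. Without the third arrays they were 4688 and 4479, and 5331 and 4914. Between WT and phyA, 3374 higher and 3575 lower calls were shared in shade, where independent lists of these lengths would share 793 and 894, and 3424 and 3596 in strong shade against 891 and 978. These pairs of comparisons have no array in common. All comparisons share 1 estimate of spread per probe set, however, so their lists are not fully independent and such expected numbers may be too low throughout. Median centring set the median of all probe sets at 0.127 and 0.142 in the 2 phyA comparisons.

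Strong shade against shade in WT compares a lower with a higher red to far-red ratio under LEDs, where red light was also dimmer and far-red light brighter. AT3G22060 rose by 2.70 ± 0.385 (adjusted p = 0.00552) and the thionin gene THI2.2 by 2.02 ± 0.257 (adjusted p = 0.00366). The GDSL lipase gene AT4G18970 fell by 1.63 ± 0.216 (adjusted p = 0.00443), and AT5G61660 fell by 1.65 ± 0.233 (adjusted p = 0.0055). These 4 kept their calls when any array of the 2 groups was left out, as did HYH, higher by 0.87, while the other 8 genes of largest change lost theirs without at least 1 array, with adjusted p up to 0.182. FHL was lower at -1.10 but reached adjusted p = 0.179 when arrays were left out in turn, its call ending without WT shade 1 or 3, without any array of WT strong shade, or with the replicate block (0.0728). No expansin or XTH gene of the 10 was called, while the list as a whole moved lower (adjusted p = 8.91e-06, but adjusted p = 0.119 with an estimated correlation); 5 were lower adjusted over the list alone. Of the 3 shade-induced genes, FHL alone was lower, and 3 adjusted over the list alone.

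The 61 higher and 89 lower calls of this comparison rest on few arrays. Median centring moved the share higher from 40.7% to 51.2%. Without WT shade 2 or 3 there were 44 and 31 calls, of which 56.8% and 64.5% were higher, and without WT strong shade 1, 2 or 3 there were 73, 42 and 50, with 71.4% higher in the set without array 2. With the third phyA arrays left out, which lowers the shared estimate of spread without touching the WT arrays, 523 were higher and 898 lower, and all 3 shade-induced genes were then among the lower.

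Strong shade and shade were next compared in phyA. With all 6 arrays limma called 0 probe sets (852 at unadjusted p under 0.05; smallest adjusted p = 0.998), and FHL and HYH had nearly equal means in both lights, FHL at 6.44 ± 0.305 and 6.44 ± 0.0749 and HYH at 3.22 and 3.25. The photosynthesis list moved lower as a whole (adjusted p = 0.00192, and 0.0342 with an estimated correlation) although 0 of its 6 members were called, over all probe sets or adjusted over the list alone. The outcome of 0 calls depends on the third arrays. Without both, 310 probe sets were higher and 564 lower, led by AT3G62950 at 2.43 and AT1G50040 at 2.05, and by the late embryogenesis gene LEA4-5 at -3.01 and AT2G37870 at -2.72. Of these, 158 higher and 296 lower were shared with the WT calls of the same model, where independent lists would share 7.13 and 22.3. The arrays left out had been seen to run against the WT score, so this overlap is partly fixed by that choice. The test of whether WT and phyA differ in this step called 0 probe sets (1631 at unadjusted p under 0.05; smallest adjusted p = 0.142), and 15, all lower, without the third arrays. In that test the expansin and XTH list moved higher (0.00153, but adjusted p = 0.265 with an estimated correlation, and 0.448 without the third arrays), with 0 of 10 genes called.

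Genotypes were then compared within each light, which asks where the loss of phytochrome A shows. In white light the differences were few. DFR was higher in phyA by 1.37 ± 0.163 (adjusted p = 0.00103), from 3.24 to 4.61, and AT5G43450 by 1.06 ± 0.121 (adjusted p = 0.000968), while the osmotin-like gene OSM34 was lower at -2.02 ± 0.223 (adjusted p = 0.000726). Of the 12 genes of largest change, only these 3 kept their calls whichever of the 4 arrays was left out, and they too missed the threshold with only the white-light groups in the model (adjusted p = 0.0633, 0.0773 and 0.0647). QQS, an orphan gene that affects starch content, stood at 1.97 (adjusted p = 0.0224), and its call ended without WT white 1 or phyA white 2 (adjusted p up to 0.343), with the replicate block (0.054) and with only the white-light groups in the model (0.123). The flavonoid list moved higher (adjusted p = 7.93e-06, and 0.0175 with an estimated correlation), with 1 of 5 genes called, and 3 higher and 1 lower adjusted over the list alone. Calls numbered 17 higher and 18 lower, or 58.8% higher after cyclic loess against 48.6% as deposited. They fell to 15, 17 and 17 without WT white 1, phyA white 1 or phyA white 2, and to 13 with only the white-light groups in the model.

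In shade the genes furthest below WT in phyA included NdhN. This gene, for a subunit of the chloroplast NDH complex, stood at 7.15 ± 0.0725 in WT and 3.95 ± 0.271 in phyA (n = 3 each), a difference of -3.19 ± 0.218 (limma adjusted p = 4.56e-07). LrgB, a plastid glycolate and glycerate transporter gene, was lower at -2.70, AT3G48420 at -2.64, AT1G65230 at -2.51, AT1G27480 at -2.47, and CaS, which encodes a thylakoid calcium-sensing protein, at -2.30 ± 0.483 (adjusted p = 0.00904). FHL was higher in phyA by 2.2 ± 0.225 (adjusted p = 1.64e-05), QQS by 2.59, AT5G60250 by 2.06 and AT1G15010 by 1.98. HYH was lower at -0.82 and WES1 higher by 0.57.

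In strong shade the genes furthest from WT included FHL, NdhN and LrgB again. FHL was higher in phyA by 3.3 ± 0.225 (adjusted p = 9.07e-08), AT1G15010 by 2.80 and QQS by 2.44. AT1G65230 stood at -3.75 ± 0.194 (adjusted p = 7.5e-09), NdhN at -3.61 ± 0.218 (adjusted p = 3.04e-08), AT3G48420 at -3.37, LrgB at -3.13 and HYH at -1.66. WES1 was higher in the mutant by 1.13 and XTH19, a cell wall enzyme gene, by 2.13 ± 0.255 (adjusted p = 2.92e-05).

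**Figure D3:**
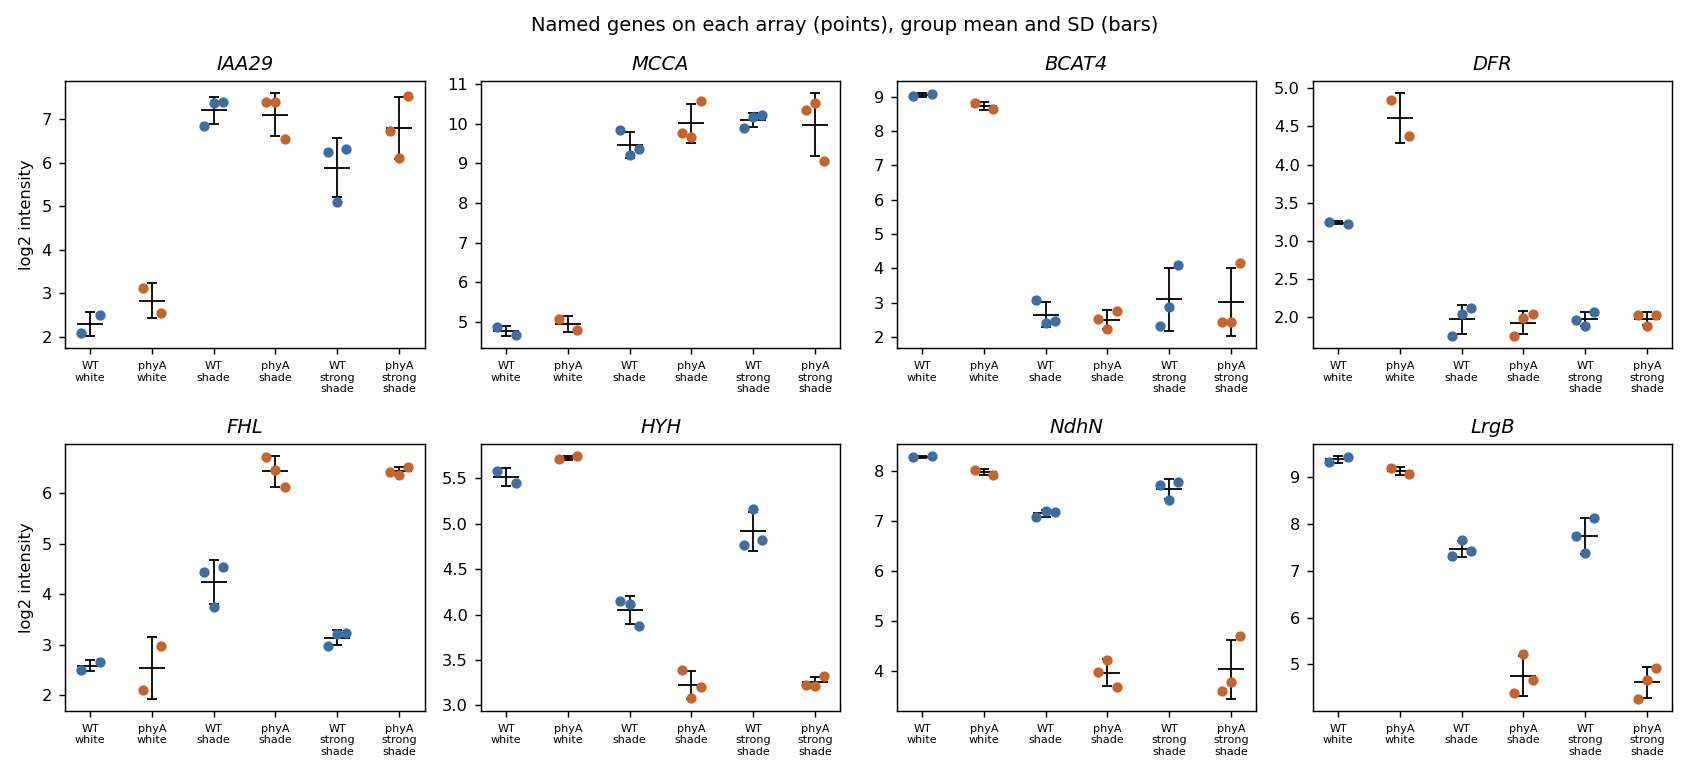
Log2 intensity (y axis) of 8 named genes on each array (points), with group mean and SD (bars), in the 6 groups (x axis). NdhN and LrgB are lower and FHL is higher in phyA than in WT in both shade conditions, where FHL reaches 6.44 in phyA in each.

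Photosynthesis and chlorophyll genes were lower in the mutant in both shade conditions. Of 6 photosynthesis genes, 3 were lower in shade (camera adjusted p = 9.92e-05) and 4 in strong shade (0.000109), or 4 in each adjusted over the list alone, with RCA at -1.06 and -1.49. Of 5 chlorophyll metabolism genes, 2 were lower in shade (0.00022) and 3 in strong shade (0.00164), or 3 in each adjusted over the list alone, with CHLI2 at -1.26 and -1.17. In shade PSAN lost its call without phyA shade 1 (adjusted p = 0.0536), PSAE-1 without WT shade 3 or phyA shade 3 (up to 0.0682), and PORB without WT shade 2 or phyA shade 1 (up to 0.0723), which leaves CHLI2 of the 2 chlorophyll calls. In strong shade LHCB4.3 held only without phyA strong shade 3 (up to 0.183 otherwise) and ended with the replicate block (0.0694). HEMA2 lost its call without WT strong shade 2 or 3 or phyA strong shade 3 (up to 0.131), with array weights (0.0502) and without the third phyA arrays (0.0888), where 2 chlorophyll genes were lower. With only the groups compared in the model, PSAE-1 and PORB in shade and LHCB4.3 and HEMA2 in strong shade missed the threshold (0.0662, 0.0705, 0.0565 and 0.106). Of 10 expansin and XTH genes, 3 were higher in strong shade, or 5 adjusted over the list alone (camera adjusted p = 0.00164, but adjusted p = 0.269 with an estimated correlation, and 0.0676 without the third arrays). The members called were XTH19, EXPB1 at 1.23 and XTH33 at 0.99.

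Calls numbered 270 higher and 816 lower in shade, and 1235 higher and 1424 lower in strong shade. Median centring moved the share higher in shade from 24.9% to 36.1%. Without WT shade 2 the shade count was 707 against 1086. Without the third arrays it was 392 and 862 in shade and 1430 and 1492 in strong shade. The shade and strong shade lists, which have no array in common but share the estimate of spread, shared 204 higher and 702 lower calls. Independent lists would share 14.7 and 51.1.

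The difference between the genotypes' responses was tested directly. FHL responded to shade more in phyA than in WT by 2.24 ± 0.355 (adjusted p = 0.00451) and to strong shade by 3.35 ± 0.355 (adjusted p = 4.85e-05). NdhN fell further in phyA by -2.88 ± 0.345 (adjusted p = 0.000691) and -3.29 ± 0.345 (adjusted p = 4.63e-05), and AT1G65230 by -2.33 and -3.57. HYH differed by -1.87 ± 0.195 in strong shade (adjusted p = 4.63e-05), where WES1 differed by 1.06 and RCA by -1.37. AT3G22060 and THI2.2, which rose with strong shade in WT, differed by -3.78 ± 0.609 and -3.12 ± 0.407. DFR fell from a higher start in phyA, and its responses differed by -1.41 and -1.36, although both genotypes ended near 1.97 in WT and 1.93 and 1.98 in phyA. These end values lie below the lower quartile of every array (2.25 to 2.36), among the dim probe sets. The genotypes differed by 1.37 in white light but by -0.04 and 0.01 in shade and strong shade. The difference of DFR responses thus restates that of white light.

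Of the lists, photosynthesis responded more strongly in phyA, with 1 of 6 genes called lower in shade and 3 in strong shade (adjusted p = 4.05e-05 in each), or 4 in each adjusted over the list alone. The flavonoid list fell further in phyA, with 1 and 3 of 5 genes called lower (7.93e-06 in each), or 4 in each adjusted over the list alone. That list was already higher as a whole in phyA in white light, with 2 arrays per genotype. Its difference of responses may therefore lie in the white-light start, as that of DFR does. The chlorophyll list had 1 of 5 in each (0.00248 in shade; 0.00912 in strong shade, but adjusted p = 0.0548 with an estimated correlation), or 2 and 3 adjusted over the list alone. The photosynthesis call in shade, LHCB4.3, held only without WT white 1, WT shade 1 or phyA shade 2 (adjusted p up to 0.232 otherwise), and the chlorophyll call in shade, CHLI2, only without phyA white 2, WT shade 1, phyA shade 1 or phyA shade 2 (up to 0.187). Both also ended with the replicate block (0.0684 and 0.0637) and with only the groups compared in the model (0.0658 and 0.0751), which leaves neither list a call in shade. In strong shade, of the counted members, PSAN lost its call when any single white-light or WT strong shade array was left out (up to 0.143), after cyclic loess (0.0835), with the replicate block (0.0706) and with only the groups compared (0.0962). CHLI2 lost it without WT white 1 or 2, phyA white 1, WT strong shade 3 or phyA strong shade 1 (up to 0.137), which leaves 0 chlorophyll calls. UF3GT lost it without WT white 1 or 2, phyA white 1, WT strong shade 2 or 3 or phyA strong shade 1 (up to 0.154), and UGT78D2 without any array other than WT strong shade 3 and phyA strong shade 1 (up to 0.163), without the third phyA arrays (0.0639) or with only the groups compared (0.0695), so of the flavonoid calls DFR alone held throughout. EXPB1 lost its call without WT white 2 (0.0501) and XTH19 without WT white 2, phyA white 1 or 2 or WT strong shade 1 (up to 0.149). The expansin and XTH list shifted higher in strong shade with 2 of 10, also adjusted over the list alone (0.012, but adjusted p = 0.355 with an estimated correlation, and 0.169 without the third arrays). With an estimated correlation, the photosynthesis calls in phyA and between genotypes held, as did the chlorophyll calls other than those in strong shade in WT and in the strong shade response difference. The flavonoid calls held except those in WT, and no auxin or expansin and XTH call held.

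**Figure D4:**
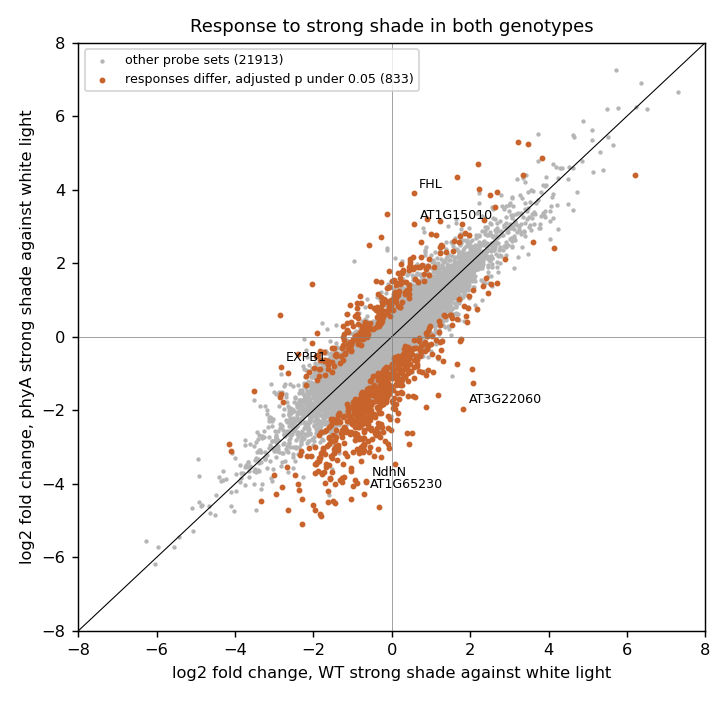
Log2 fold change of each probe set from white light to strong shade in WT (x axis) and phyA (y axis), with the 833 probe sets whose responses differed at adjusted p under 0.05 in colour and the diagonal of equal response. Most coloured points, 579 of 833, lie below the diagonal.

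In numbers, 38 probe sets responded more positively and 201 more negatively to shade in phyA, and 254 and 579 to strong shade. Without the third arrays these were 86 and 281, and 479 and 757. The shade count of 239 was 156 without WT white 1, 125 without WT white 2, 109 without phyA white 1, 129 without phyA white 2 and 153 without WT shade 2. The strong shade count of 833 was 471 without WT white 2, 463 without phyA white 1 and 533 without phyA white 2.

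Among 10850 probe sets that responded to shade on average over the genotypes, the response was larger in phyA for 62.7%, with a median ratio of phyA to WT of 1.12. The 3 phyA shade arrays gave ratios of 1.09, 1.06 and 1.21. For 11229 probe sets in strong shade the share was 54.2% and the ratio 1.04, with 1.11, 1.13 and 0.878 for the 3 arrays. The spread between these arrays comes mainly from the third, which lay apart from its group; the others lie above 1. Genes that rose had a median ratio of 1.12 in strong shade and genes that fell 0.938, both with the third array included.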

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

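The tests of an exchange of labels, of a shared shift, of the number of arrays and of green tissue were chosen only after the result was seen, as were the splits of the samples for the differences between strong shade and shade in phyA and between genotypes.

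Shade and strong shade responses were flagged because they differed between WT and phyA by the test of the difference itself, for 239 probe sets in shade and 833 in strong shade. In shade the response was more positive in phyA for FHL (2.24), OSM34 (1.72), AT3G45730 (1.65), AT2G18600 (1.63), AT4G16670 (1.57) and AT5G60250 (1.39). It was more negative for NdhN (-2.88), AT1G27480 (-2.87), AT3G48420 (-2.64), LrgB (-2.45), AT1G65230 (-2.33) and AT2G04790 (-2.28). For OSM34 the genotypes differed by -2.02 in white light but by -0.30 in shade. Its difference of responses thus mostly restates that of white light. OSM34 lost its call without phyA white 1 (adjusted p = 0.0596), AT4G16670 without WT white 1 or phyA white 1 (up to 0.0798), and AT3G45730 without any of 9 of the 10 arrays, phyA shade 1 being the exception (up to 0.202). AT3G45730 also missed the threshold with the replicate block (limma adjusted p = 0.0858) and after median centring (0.0523). In strong shade the response was more positive in phyA for FHL (3.35), AT1G15010 (2.49), AT4G02360 (2.3), EXPB1 (2.02), AT4G18970 (2.02) and AT5G61660 (1.94). It was more negative for AT3G22060 (-3.78), AT1G65230 (-3.57), AT3G48420 (-3.37), NdhN (-3.29), AT1G27480 (-3.27) and THI2.2 (-3.12). EXPB1 lost its call without WT white 2 (adjusted p = 0.0501), and AT4G02360 without WT white 1, phyA white 1 or phyA white 2 (up to 0.0866).

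Gene lists differed in the same way. In shade the median difference of responses was -0.53 for photosynthesis genes, -0.29 for chlorophyll metabolism genes and -0.72 for flavonoid and anthocyanin genes. In strong shade it was 0.72 for expansin and XTH genes, -0.69 for photosynthesis genes, -0.60 for chlorophyll metabolism genes and -0.75 for flavonoid and anthocyanin genes. From shade to strong shade it was 0.61 for expansin and XTH genes. The expansin and XTH shifts and the chlorophyll shift in strong shade did not pass with an estimated correlation (adjusted p = 0.355, 0.265 and 0.0548), and without the third phyA arrays the 2 expansin and XTH medians were 0.37 and 0.22.

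The third phyA arrays of shade and strong shade each lay with the other group. An exchange of their labels needs both to be out of place in opposite directions, and on the WT score the third phyA shade array exceeded the third phyA strong shade array by 1.66, where the means of arrays 1 and 2 differed by -1.24. A disturbance that both arrays shared would move them the same way, whereas their deviations across probe sets were opposed (r = -0.579), which restates the pattern and adds no separate evidence. An exchange may account for the pattern, but the score was built after the arrays had been seen to stand apart, and a true spread of responses in phyA was not tested. The 10 splits of the 6 phyA arrays are too few for a share under 0.05: the real one gave 0 calls, and the split that puts the third phyA strong shade array with phyA shade 1 and 2 gave 2439, which points to a structure of the samples but restates the pattern, since it regroups the arrays already seen to stand apart.

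Genotype differences numbered 35 in white light and 2659 in strong shade. Fewer white-light arrays could lower the count there. With only 2 arrays per genotype used in strong shade, the 9 possible choices gave 1446 to 2172 calls, with a median of 1750, and in shade 504 to 869. The number of arrays thus does not account for the whole gap, while a biological dependence on light and any batch of white-light samples remain open and untested. The 10 splits of 3 arrays against 3 are too few for a share under 0.05: in strong shade the real split, 1 of 10, gave 2659 and the highest other 0, and in shade the real split, again 1 of 10, gave 1086 and the highest other 15.

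NdhN, LrgB, CaS and AT3G48420 were lower in phyA in strong shade, at -3.61, -3.13, -2.82 and -3.37. Less green tissue in the phyA samples could lower all transcripts of photosynthetic cells. To give the full size of these falls, it would need the 6 photosynthesis genes to fall about as far. Their median was -0.58 with an SD of 0.492, so that the median less the SD, -1.07, stays well above the smallest of the 4 falls. The 4 genes were picked for their large falls, however, which a list fixed beforehand would hardly reach. All 6 list genes were below 0, from -0.159 for LHCB4.1 to -1.486 for RCA. A smaller part from less green tissue therefore remains open. A direct dependence of these genes on phytochrome A remains open and was not tested.

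For the other comparisons of 3 arrays against 3, WT strong shade against shade gave 150 calls in the real split, 1 of 10, and 0 in the highest other, and these splits too are too few for a share under 0.05. For the difference between the genotypes in that step the real count is 0, so all 100 of 100 drawn splits reach it whatever the data, and the number says nothing about chance. The highest count in another split was 3507. Splits that exchange the genotype labels in only 1 light turn this test into the sum of the genotype differences of both lights. Such a count can come from those differences and is not evidence of another structure of the samples.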

How the results depend on the processing

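Leaving out the third phyA arrays was chosen only after the result was seen; the other alternatives were planned. No call of a named gene or list turned direction. The larger direction of a comparison's calls did turn. Median centring set the share higher at 52.4% and 57.3% for shade and strong shade against white light in WT, 51.2% for WT strong shade against shade and 53.1% for the genotypes in white light. For the genotypes in white light the share was 58.8% after cyclic loess, 59.4% with trended and robust variances, 51.6% with the replicate block, 51.0% without the third phyA arrays, and 60.0% and 64.7% without WT white 1 and phyA white 2, against 48.6%. It was 56.8%, 64.5% and 71.4% for WT strong shade against shade without WT shade 2, WT shade 3 and WT strong shade 2, 50.3% for WT shade against white light without dim probe sets, and 52.3% for the genotypes in strong shade with array weights. In phyA, shade and strong shade against white light turned to fewer higher than lower calls after cyclic loess (46.5% and 46.3%), at a log2 fold of at least 1 (47.4% and 47.5%) and without phyA white 2 (48.2% and 49.6%). Counts against white light stayed within 1.5 times under each alternative other than a log2 fold change of at least 1, which by construction lowered counts to 3239 and 3723 in WT, 4030 and 4161 in phyA, 68 for WT strong shade against shade, 321 and 691 for phyA against WT in shade and strong shade, and 535 for the difference of strong shade responses. Array weights gave 1305 for WT strong shade against shade, 56 and 1642 for phyA against WT in white light and shade, and 429, 1361 and 6 for the differences of responses to shade, to strong shade and between them. A model on only the groups compared gave 848 for WT strong shade against shade and 13 for the genotypes in white light, where leaving out dim probe sets gave 21. Trended and robust variances gave 4 for the last difference, against 0. Without the third phyA arrays the counts were 1421 for WT and 874 for phyA strong shade against shade, and 367 and 15 for the differences of responses to shade and between the shades. Leaving out each array in turn gave 31 to 123 for WT strong shade against shade, 15 to 24, 707 to 968 for the genotypes in white light and shade, and 109 to 270, 463 to 926 and 0 to 3 for the differences of responses. Fewer arrays lower such counts by construction, but some rose, to 270 without phyA shade 2, 926 without phyA strong shade 3 and 3 without WT strong shade 2, and the cause was not tested. Of 34 gene list calls, 18 held with an estimated correlation, 30 without the third arrays, 33 after cyclic loess and 34 after median centring. Of the calls of named genes, 1673 were kept and 188 lost over all arrays left out, and 301 kept and 21 lost with only the groups compared. The response ratio moved by less than 1 SD throughout. That SD is over the 3 phyA arrays of a light (0.138 in strong shade) and is widened by the third array there. It therefore cannot show whether the ratio depends on that array. Replicate numbers do not pair the samples: of 36 same-numbered pairs of different groups, 7 had deviations that correlated over 0.1 (range -0.579 to 0.318), and 4 arrays correlated best with their own number. With the replicate block the counts were 7950 and 8625 for shade and strong shade against white light in WT, 9012 and 9293 in phyA, 108 and 0 for strong shade against shade, 31, 989 and 2443 for the genotypes in white light, shade and strong shade, and 185, 719 and 0 for the differences of responses, all within 1.5 times, and 33 list calls held, that of photosynthesis in WT strong shade ending (adjusted p = 0.0562). Low signal over background limits dim probe sets, whose log2 changes are compressed.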

Other observations

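The tests of gene families, of the probe sets called in all 3 lights and of a low-energy state were chosen only after the result was seen.

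Most of the measured autophagy genes were higher in both shade conditions in both genotypes. Of the 8 measured ATG genes, 6 rose in WT in shade and 6 in strong shade, and 8 in phyA in each (camera adjusted p = 0.000351, 0.000565, 0.000276 and 0.000351, but adjusted p = 0.607 with an estimated correlation in WT strong shade), with median log2 changes of 1.13, 1.12, 1.23 and 1.25. All but ATG3 belong to the ATG8 subfamily, so the counts mostly cover related genes. In WT shade and strong shade, limma called neither ATG3 (adjusted p = 0.097 and 0.0766) nor ATG8H (adjusted p = 0.0613 and 0.196). ATG8B, which encodes a membrane-bound protein of the autophagosome, rose by 2.80 in WT and 3.85 in phyA in strong shade, and ATG8E by 1.97 and 1.71. Of 69 genes encoded in the plastid, 17 were lower in phyA than in WT in strong shade (9.93e-09, but adjusted p = 0.607 with an estimated correlation), with a median of -0.34. Among smaller lists, the cytokinin response regulator genes ARR15 and RR16 fell in both shades in WT, at -0.77 and -0.82 in shade, and the ethylene gene RTE1 rose by 0.94. STZ, a zinc finger gene of the touch and wound list, rose by 1.32 in shade and 1.92 in strong shade in WT, and AUR1, a mitotic kinase gene, stood at -1.68 and -2.38. YUC2, an auxin synthesis gene, rose by 0.94 in shade, and the cold gene COR15B stood at -2.13 in strong shade. PDF1.2 at 0.04 and SAG101 at 0.10, the measured jasmonate and salicylate genes, did not pass in WT shade.

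Genotype differences were present in all 3 lights for 11 probe sets, 3 higher and 8 lower in phyA, chosen after their values were seen. QQS was higher by 1.97, 2.59 and 2.44 in white light, shade and strong shade, while AT3G49140 was lower at -2.05, -1.3 and -1.27. An unnamed probe set of those lower in phyA stood at -3.00, -6.18 and -5.92 (largest limma adjusted p = 1.66e-06), and an unnamed one of those higher at 2.24, 2.14 and 2.41. No gene is listed for either, so whether one of them measures PHYA cannot be told from the annotation used. Several of these white-light calls, those of QQS and AT3G49140 among them, end when a white-light array is left out.

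A hypothesis is that seedlings under the LED lights were in a low-energy state, since all 3 measured dark and low-energy genes rose there in both genotypes. It predicts a rise of autophagy genes, which carbon shortage is known to induce. Of the 8 ATG genes, 6, all of the ATG8 subfamily, were called higher in WT strong shade against white light. This is consistent with a low-energy state, but the family did not stand apart from other genes with an estimated correlation (adjusted p = 0.607). Light intensity, light source and red to far-red ratio change together between white light and the LED conditions, so the design does not say which of them the rise would follow. The 2 LED conditions differ in red light, far-red light and their ratio. Between them limma called no ATG gene in WT, the largest change being that of ATG8E at 0.40 (adjusted p = 0.268). This does not settle which part of the change from white light matters.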
